A study of Homo sapiens with 4 samples.

How the data were processed

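MicroRNA levels were measured in 4 human oesophageal squamous cell carcinoma lines, KYSE-450, KYSE-520, KYSE-890 and KYSE-960, with 1 one-colour oligonucleotide array per line. Per the labels' protocols, 500 ng of total RNA per line, isolated by the guanidinium thiocyanate and phenol-chloroform procedure, was labelled with the dye Hy5, hybridized for 16 h at 32 °C to a chip of human microRNA probes and read on a ProScanArray scanner. The lines had been grown at 37 °C and 5% CO2 in medium with 5% serum.

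The deposited table holds 1 intensity per feature and array for 856 features, as scanner brightness on a linear scale. The unit, the handling of replicate spots, any background subtraction and any scaling between arrays are not given in the sources used here. All deposited intensities were multiples of 0.5, 49.3% were not whole numbers, none was missing, 0 or negative, and 2 lay at 65000 or above, close to the 16-bit ceiling of 65535. These values look like means of 2 raw spot readings, or medians of an even number of them, with the background left in. A probe at the ceiling understates its target RNA, and the background left in draws ratios of dim probes towards 1.

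Features are identified only by miRBase mature-sequence accessions (MIMAT numbers). The table does not pair these with microRNA names, and none of the 856 was found in the gene table used for names (0 matches), so features are given by accession, with no gene, arm or genomic position. For the same reason 28 lists of microRNA families, clusters and cell-type markers that had been fixed before the data were examined could not be matched, and the planned shifts of those lists, with their percentiles among 10000 random lists, were not run. These lists included microRNA names drawn from other small RNAs. Whether any feature given here, the brightest included, belongs to that list could not be checked.

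The rules for scaling, floor, thresholds and named features were also fixed before the data were examined. The deposited values were to be used unscaled only if the medians over features at or above the array median on all 4 arrays (184 features) lay within 0.1 log2 of each other. They spanned 0.87 log2, so the arrays were quantile-normalized with limma 3.58.1 in R 4.3.3. Quantile normalization gives every array the same set of values and can only move features relative to each other. It shifted the median feature by between -0.09 and 0.07 log2. Features above background on at least 1 array moved by a median of -0.16 log2 in KYSE-450, -0.67 in KYSE-520, 0.60 in KYSE-890 and 0.70 in KYSE-960, so the unscaled values are given beside the normalized ones. The median of each array served as the floor, values below it were raised to it, and 143 features below it on all 4 arrays were left out, leaving 713. Values were then taken to log2.

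A feature stood apart in a line when its value there was at least 2-fold above the highest, or below the lowest, of the other 3 lines. For each of the 6 pairs of lines, features that differed by at least 2-fold were counted. With 1 array per line there is no spread between replicates, so no difference between lines has a replicate check and no p-value is given for any line. Correlations between arrays are across features, which are not independent replicates. Up to 6 features per line and direction with the largest gap to the nearest other line were to be named, together with those among the 20 brightest on all 4 arrays. Because no names were available, at most 2 per line and direction are printed.

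After the data had been seen, a background threshold was added for each array, at its median plus 3 times an SD taken from the dim side of the median. It lay at 139 intensity units in KYSE-450, 150.0 in KYSE-520, 128.5 in KYSE-890 and 130.0 in KYSE-960. A feature under it is called not above background, and a fold against such a feature is given as "at least", computed from the higher of that feature's own value and the dimmest feature above background on the same array. The fixed alternatives were other scalings, other floors, a filter, a 4-fold threshold, an added constant of 16 and leaving out each line in turn. The background threshold as floor and a normexp correction with an offset of 50 were added later.

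The counting of features that stood apart was tested on simulated arrays of 856 features with the measured background and an assumed multiplicative error of 10%, with KYSE-520 as the changed line. Without any change, 0 features were called on average. This follows from the assumed noise and does not measure the rate of false calls on the real arrays. With 20 bright features raised and 20 lowered 4-fold, 70.2% were recovered after quantile normalization and 83.8% without scaling. At 8-fold these shares were 86.5% and 91.1%. Quantile normalization made 0.45 wrong calls per run at 4-fold and 3.65 at 8-fold. With all 40 of the changed features raised 4-fold, it recovered 13.1% and made 4.1 wrong calls per run, while no scaling recovered 99.6%. At 8-fold quantile normalization recovered 65.1% and made 20.5 wrong calls per run. Without scaling, wrong calls averaged 0.0 in each of these settings. The simulated arrays had equal overall brightness, which favours the unscaled values. Calculations used Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6. The precision of single values is limited by the number of arrays.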

Results

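The data comprised 4 microRNA arrays, each hybridized with total RNA of a different oesophageal squamous cell carcinoma line of the KYSE series: KYSE-450, KYSE-520, KYSE-890 and KYSE-960. These are established lines cultured from human tumours of the squamous lining of the gullet. MicroRNAs are short RNAs that repress messenger RNAs by base pairing. No treatment, normal tissue or second array of a line was part of the design. With 1 array per line no difference has a replicate check and no p-value is given, and the comparison the design allows is of the microRNA profile between lines.

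A minority of the features on the chip gave signal above background in these lines. The threshold lies above the median of each array's own features, so on any single array only a minority can pass it. Of 856 features, 163 (19%) were above background on at least 1 array and 75 on all 4. KYSE-520 had the most features above background, 145, followed by KYSE-450 with 117, KYSE-890 with 95 and KYSE-960 with 94. Of the 41 features above background in a single line, 26 were so in KYSE-520, 7 in KYSE-890, 5 in KYSE-960 and 3 in KYSE-450. Of the 31 features above background in exactly 2 lines, 23 were so in KYSE-450 and KYSE-520 and 0 in KYSE-890 and KYSE-960.

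The arrays differed in the brightness of the features above background and much less in the background itself. The median intensity over all features was 78.8 in KYSE-450, 85.5 in KYSE-520, 80.5 in KYSE-890 and 77.5 in KYSE-960. The median over each array's own features above background was 497 for 117 features in KYSE-450, 454 for 145 in KYSE-520, 292.5 for 95 in KYSE-890 and 262 for 94 in KYSE-960. These sets differ, and of the 111 features above background in both KYSE-450 and KYSE-520, 83 were brighter in KYSE-520. Summed intensity was 285341 in KYSE-450, 349156 in KYSE-520, 192550 in KYSE-890 and 180682 in KYSE-960. One feature, MIMAT0006766, supplied 19.3%, 16.4%, 33.9% and 36.2% of these sums, respectively.

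**Figure D1:**
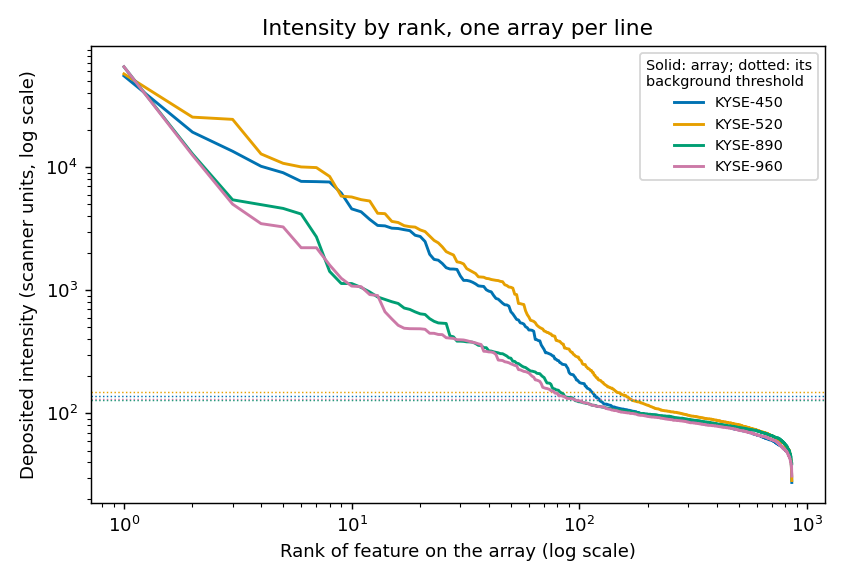
Deposited intensity (scanner units, log scale) of the 856 features of each array against their rank on that array (log scale), with 1 solid line per cell line and its background threshold dotted. The curves of KYSE-450 and KYSE-520 lie above those of KYSE-890 and KYSE-960 from about rank 2 down to the background, where all 4 meet between 77.5 and 85.5 at the median.

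The brightest features were partly common to all 4 lines. Of the 20 brightest features of each line, 35 in all, 8 were among the 20 brightest of every line. MIMAT0006766 ranked first on each array, with 55201 in KYSE-450, 57264 in KYSE-520, 65348 in KYSE-890 and 65472 in KYSE-960. The last 2 values lay near the scanner's ceiling, so the order of the lines for this feature is not established. MIMAT0005946 ranked second in KYSE-450 and KYSE-520, at 19269 and 25504, and measured 1424 in KYSE-890 and 2217 in KYSE-960. MIMAT0004973 measured between 4964 in KYSE-890 and 10051 in KYSE-520, a 2.03-fold span in the deposited values. MIMAT0000418 spanned 3.09-fold and MIMAT0000078 spanned 3.03-fold, each highest in KYSE-520 and lowest in KYSE-960. MIMAT0000080, MIMAT0000062 and MIMAT0000065 spanned 5.75-fold, 9.31-fold and 11.9-fold with the same lines at the extremes. Quantile normalization changed both the spans and the order of the lines. MIMAT0005946 then spanned 3.69-fold and stayed lowest in KYSE-890, and MIMAT0000065 spanned 1.95-fold and stayed highest in KYSE-520 and lowest in KYSE-960. MIMAT0000062 spanned 1.53-fold, lowest in KYSE-960 as before but highest in KYSE-890. MIMAT0000418 and MIMAT0000080 turned to highest in KYSE-890 and lowest in KYSE-450, spanning 2.01-fold and 2.07-fold. MIMAT0000078, at 1.93-fold, turned to lowest in KYSE-450 and equally high in KYSE-890 and KYSE-960, and MIMAT0004973 turned to lowest in KYSE-450 and highest in KYSE-960, spanning 2.54-fold.

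KYSE-450 resembled KYSE-520, and KYSE-890 resembled KYSE-960, more closely than any other pair. Over the 163 features above background on at least 1 array, Pearson's r of the deposited log2 intensities was 0.92 for KYSE-450 with KYSE-520 and 0.93 for KYSE-890 with KYSE-960. It was 0.69 for KYSE-450 with KYSE-890, 0.75 for KYSE-450 with KYSE-960, 0.62 for KYSE-520 with KYSE-890 and 0.65 for KYSE-520 with KYSE-960. Spearman's rho, which no monotone rescaling of an array can change, was 0.87 in both of the closest pairs and between 0.48 and 0.66 in the other 4. Ranks can still change where features fall into the background of a dimmer array, and KYSE-890 and KYSE-960 were the dimmer arrays. Of the 163 features, 23 were above background only in KYSE-450 and KYSE-520, 26 only in KYSE-520 and 3 only in KYSE-450. Another 7 were so only in KYSE-890 and 5 only in KYSE-960. How far this lowered rho was not tested. Over all 713 analysed features, most of them at background, rho after quantile normalization and flooring separated the pairs less, at 0.59 and 0.47 in the closest pairs and 0.38 to 0.43 in the others. These correlations are across features within pairs of arrays. Of the 20 brightest features, KYSE-450 and KYSE-520 had 17 in common and KYSE-890 and KYSE-960 had 14, against 9 to 12 in the remaining pairs.

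Counts of differing features were also lower in these 2 pairs than in the other 4. After quantile normalization, 20 of 713 features differed by at least 2-fold between KYSE-450 and KYSE-520, 7 higher in KYSE-450 and 13 higher in KYSE-520. Between KYSE-890 and KYSE-960 the count was 36, with 14 higher in KYSE-890. KYSE-450 differed from KYSE-890 in 77 features, 36 of them higher in KYSE-450, and from KYSE-960 in 80, with 40 higher in each line. KYSE-520 differed from KYSE-890 in 85 features, 46 of them higher in KYSE-520, and from KYSE-960 in 87, 43 of them higher in KYSE-520. The near balance of directions is a property of quantile normalization. In the deposited values 62 features were higher in KYSE-450 than in KYSE-890 and 8 lower, and 63 were higher than in KYSE-960 and 1 lower. Likewise 89 were higher in KYSE-520 than in KYSE-890 and 6 lower, and 95 were higher than in KYSE-960 and 2 lower. The deposited values also gave 36 differing features between KYSE-450 and KYSE-520, 6 higher in KYSE-450 and 30 in KYSE-520. They gave 12 between KYSE-890 and KYSE-960, 9 higher in KYSE-890 and 3 in KYSE-960, where the normalized values had more features higher in KYSE-960, so which of the 2 closest pairs had fewer differences depends on the scaling.

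**Figure D2:**
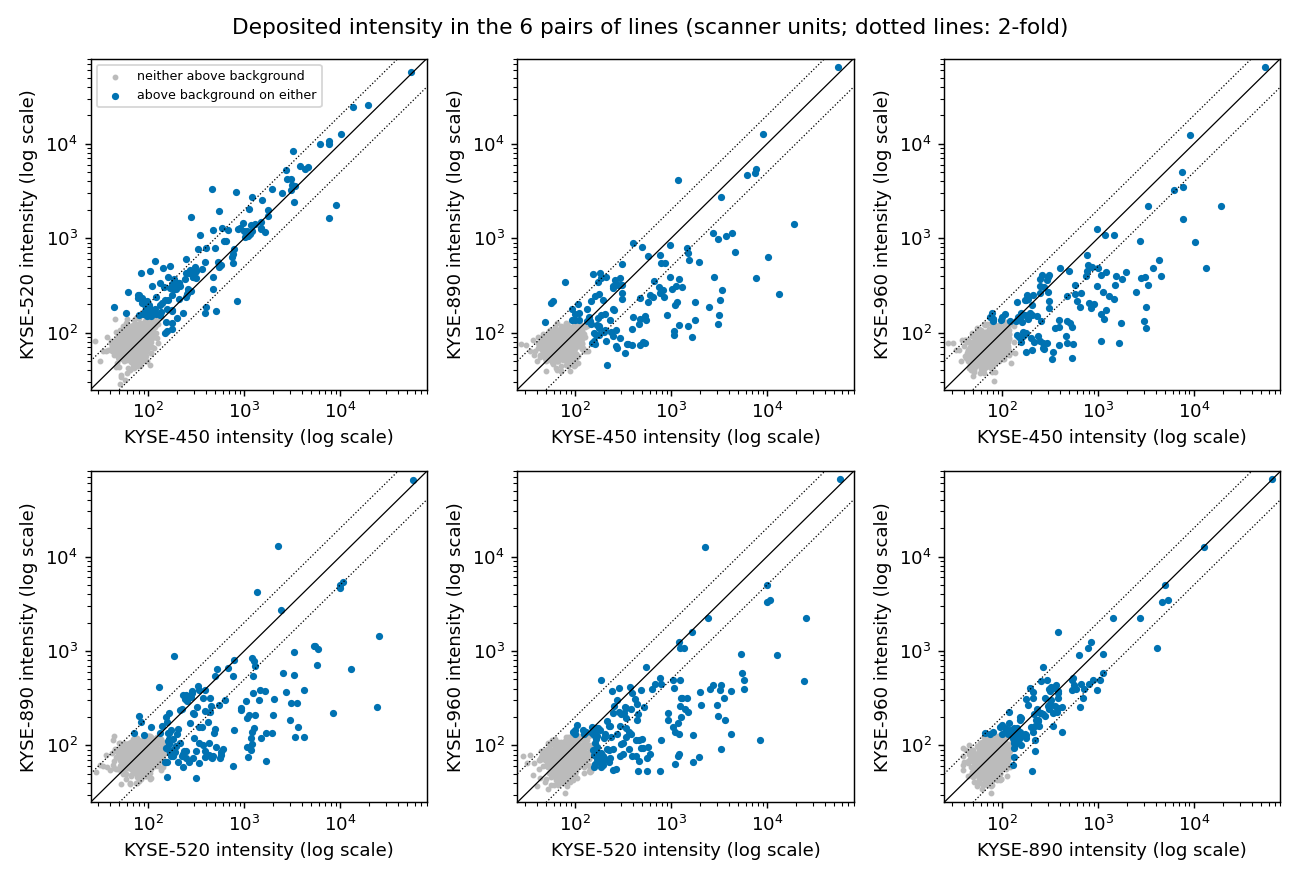
Deposited intensity (scanner units, log scales) of every feature in the 6 pairs of lines, with the line of equality solid and 2-fold differences dotted. Points above background on either array (blue) lie close to equality for KYSE-450 with KYSE-520 (r = 0.92) and KYSE-890 with KYSE-960 (r = 0.93) and scatter mostly towards the KYSE-450 or KYSE-520 side in the other 4 pairs.

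Few features stood apart in a single line by 2-fold or more from all 3 others. After quantile normalization 39 such calls were made, 26 higher and 13 lower (66.7% higher). The deposited values gave 33 higher and 10 lower (76.7% higher). These counts depended on which other lines were present. Leaving out a line can only keep or raise them, so the size of a rise is informative and its direction is not. Leaving out KYSE-450 raised the calls in KYSE-520 from 10 to 38 higher and from 3 to 25 lower, and leaving out KYSE-520 raised those in KYSE-450 from 2 to 31 higher and from 0 to 26 lower. Leaving out KYSE-960 raised those in KYSE-890 from 9 to 36 higher and from 6 to 31 lower, and leaving out KYSE-890 raised those in KYSE-960 from 5 to 33 higher and from 4 to 34 lower.

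In KYSE-520, 10 features stood apart as higher and 3 as lower, whereas the deposited values gave 26 higher and 2 lower, among them 10 and 2 of the same features. MIMAT0000086 measured 3350 in KYSE-520 against 465 in KYSE-450, and was not above background in KYSE-890 or KYSE-960. It was 5.33-fold above KYSE-450 after normalization and 7.20-fold before. MIMAT0000100 measured 1683 against 276 in KYSE-450 and was likewise not above background in KYSE-890 and KYSE-960, a difference from KYSE-450 of 3.89-fold after and 6.10-fold before normalization. In the other direction, MIMAT0000266 measured 2253 in KYSE-520, against 9019 in KYSE-450, 12821 in KYSE-890 and 12518 in KYSE-960. It lay 5.67-fold below KYSE-450 after normalization and 4.0-fold before, while most features above background were brighter in KYSE-520 than in the other lines. MIMAT0005864 measured 185 in KYSE-520, 399 in KYSE-450, 883 in KYSE-890 and 488 in KYSE-960, and lay 2.51-fold below KYSE-450 after and 2.16-fold before normalization.

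In KYSE-890, 9 features stood apart as higher and 6 as lower, whereas the deposited values gave 3 and 3, among them 3 and 1 of the same features. Of the 9 higher, 1 was above background on no array. MIMAT0005880 measured 419 in KYSE-890, and 153 in KYSE-450 and 139.5 in KYSE-960, both just over the background threshold. In KYSE-520, at 129.5, this feature was not above background. It was 4.52-fold above KYSE-960, the nearest line after normalization, and 2.74-fold above KYSE-450, the nearest before. MIMAT0004776 measured 204 in KYSE-890 and was not above background in the other 3 lines, and was at least 1.59-fold above KYSE-960 after normalization and at least 1.35-fold above KYSE-520 before. MIMAT0005938 measured 256 in KYSE-890 and 482.5 in KYSE-960, against 13477 in KYSE-450 and 24463 in KYSE-520. Its gap between KYSE-890 and KYSE-960 was 3.30-fold after and 1.88-fold before normalization. MIMAT0000680 was not above background in KYSE-890 and measured 227 in KYSE-960, 1489 in KYSE-450 and 1501 in KYSE-520, with KYSE-890 at least 2.43-fold below KYSE-960 after and at least 1.75-fold below before normalization.

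In KYSE-960, 5 features stood apart as higher and 4 as lower, whereas the deposited values gave 0 and 4, among them 0 and 1 of the same features. Of the 5 higher, 1 was above background on no array. MIMAT0000081 was 3.76-fold above KYSE-450 after normalization, but its deposited intensity was 669.5 in KYSE-960 and 760.5 in KYSE-450, so its direction turned with the scaling. MIMAT0004682 measured 138.5 in KYSE-960, just over the background threshold of that array, and was not above background elsewhere. MIMAT0000076 was not above background in KYSE-960, at 113, and measured 220.5 in KYSE-890, 3197 in KYSE-450 and 8415 in KYSE-520. KYSE-960 lay at least 1.89-fold below KYSE-890 for this feature after and at least 1.68-fold below before normalization. MIMAT0000425 was not above background in KYSE-960 and measured 134.5 in KYSE-890, 544.5 in KYSE-450 and 1936 in KYSE-520, and its gap to KYSE-890 was at least 1.03-fold under both scalings.

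In KYSE-450, 2 features stood apart as higher and 0 as lower, whereas the deposited values gave 4 and 1, among them 1 and 0 of the same features. MIMAT0004504 measured 506 in KYSE-450 and 170.5 in KYSE-520, and was not above background in KYSE-890 or KYSE-960. It was at least 2.13-fold above KYSE-960, the nearest line after normalization, and 2.97-fold above KYSE-520 before. The gap shrank to 0.47 log2, under 2-fold, with the 75th percentiles of shared features set equal. MIMAT0000097 measured 476 in KYSE-450 and 290 in KYSE-520 and was not above background in the other two lines, a difference from KYSE-520 of 2.05-fold after and 1.64-fold before normalization.

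Of the 14 line-specific features named here, 5 kept a gap of at least 2-fold under every alternative scaling, floor or filter that retained them: MIMAT0000086, MIMAT0000100, MIMAT0000266 and MIMAT0005864 in KYSE-520 and MIMAT0005880 in KYSE-890. The other 9 had a gap under 2-fold in at least 1 alternative.

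**Figure D3:**
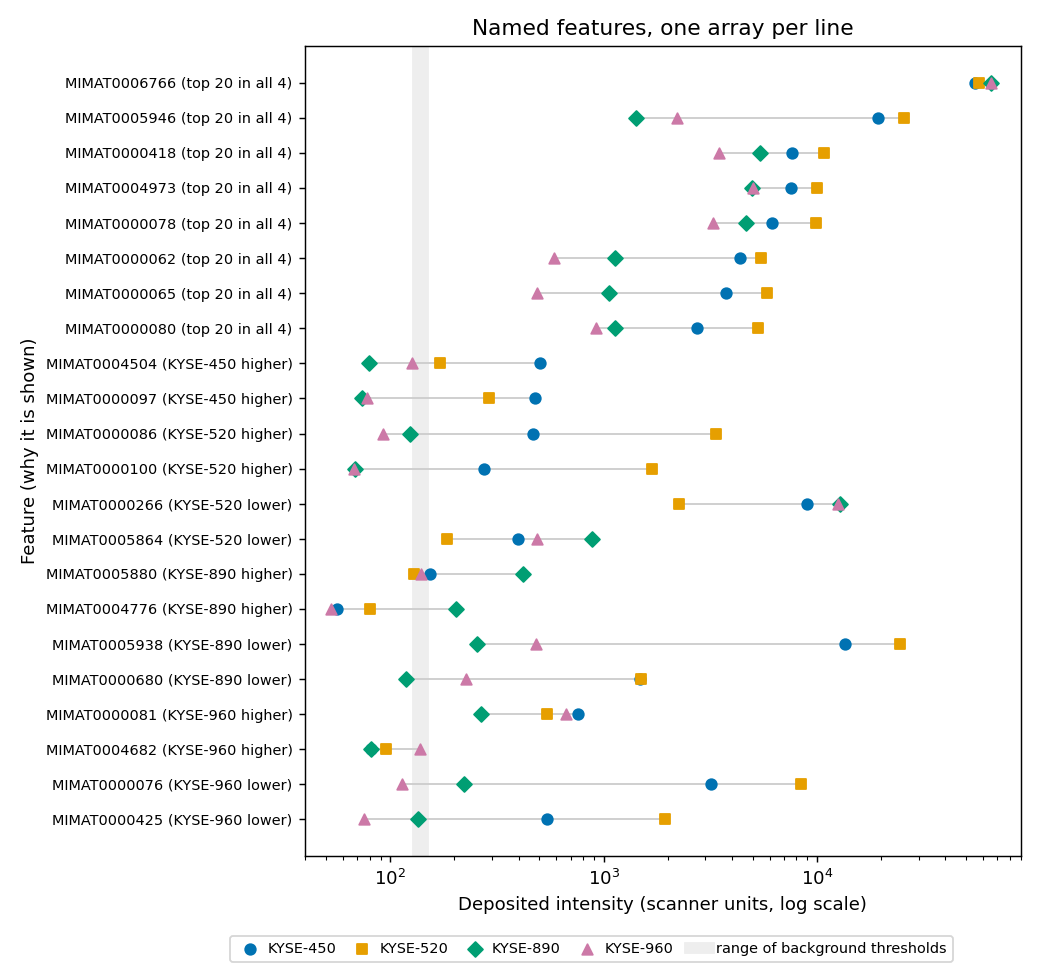
Deposited intensity (scanner units, log scale) of the named features in the 4 lines, 1 marker per array, with the range of the 4 background thresholds shaded grey. MIMAT0000266 is lowest in KYSE-520 (2253) and at least 9019 in the other 3 lines, and MIMAT0005938 runs from 256 in KYSE-890 to 24463 in KYSE-520.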

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

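Counts are of features that stood apart or that differed between a pair of lines, at 2-fold unless stated, and of brightest features common to all lines. The causes of changes were not tested except where the construction of a setting shows them. Alternatives using the background threshold or normexp were chosen after seeing the data. No paired analysis was possible because each line had 1 array. The planned shifts of microRNA lists were not run, since no feature could be named. For features that stood apart and for pairwise differences, the alternatives, leave-outs included, gave 192 counts. Of these, 120 stayed within 1.5 times the main count (68 of features that stood apart and 52 of pairwise differences). Leave-outs can only keep or raise a count, and the 4-fold threshold can only keep or lower it. The 2 alternative counts of brightest features are not among the 192, and both moved by more than 1.5 times.

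With the deposited values, features that stood apart as higher numbered 4 in KYSE-450, 26 in KYSE-520, 3 in KYSE-890 and 0 in KYSE-960, with 1 lower in KYSE-450 and 3 lower in KYSE-890, and 36 differed between KYSE-450 and KYSE-520 and 12 between KYSE-890 and KYSE-960. With the background threshold as floor on the deposited values, these counts were 4, 19, 2 and 0 higher and 3 lower in KYSE-890, and 10 differed between KYSE-890 and KYSE-960. With the background threshold as floor after quantile normalization, 1, 6, 4 and 3 were higher in the 4 lines and 2 were lower in KYSE-960, while 51 differed between KYSE-450 and KYSE-960 and 17 between KYSE-890 and KYSE-960. Setting the medians over the 184 shared features equal gave 5 higher and 1 lower in KYSE-450, 5 higher and 2 lower in KYSE-890 and 0 higher in KYSE-960, with 171 differing between KYSE-520 and KYSE-890 and 14 between KYSE-890 and KYSE-960. Setting the 75th percentiles of those features equal multiplies the background too, and 630, 643, 634 and 641 features then differed in the 4 pairs that join KYSE-450 or KYSE-520 to KYSE-890 or KYSE-960, and 12 between KYSE-890 and KYSE-960. Under it the higher and lower calls were 1 and 6 in KYSE-450, 5 and 8 in KYSE-520, 5 and 2 in KYSE-890, and 2 and 1 in KYSE-960.

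Requiring signal at or above the floor in all 4 lines left 0 higher in KYSE-450, 4 in KYSE-520 and 5 in KYSE-890, and 10 differing between KYSE-450 and KYSE-520. Without a floor, 1 was lower in KYSE-450 and 56 differed between KYSE-890 and KYSE-960. Adding 16 before log2, or normexp before quantile normalization, left 1 higher in KYSE-450. At 4-fold, KYSE-520 kept 1 higher and 1 lower and KYSE-890 kept 1 higher, with 0 in the other directions and lines, and the pairs gave 4 (KYSE-450 and KYSE-520), 30 and 15 (KYSE-450 with KYSE-890 and KYSE-960), 37 and 27 (KYSE-520 with the same) and 3. Of the brightest features, 5 of the top 10 and 27 of the top 50 were common to all 4 lines. Leaving out each other line in turn gave 3 to 31 higher and 0 to 26 lower in KYSE-450, 11 to 38 and 3 to 25 in KYSE-520, 9 to 36 and 8 to 31 in KYSE-890, and 7 to 33 and 4 to 34 in KYSE-960. The gap of MIMAT0000081 in KYSE-960 turned to -0.18 log2 in the deposited values with either floor, and that of MIMAT0004682 in KYSE-960 turned to -0.12 log2 in the deposited values with the background threshold as floor. The lowest gaps of the other named features that passed under 2-fold were 0.76 log2 for MIMAT0000076, 0.71 for MIMAT0000097, 0.04 for MIMAT0000425, 0.82 for MIMAT0000680, 0.47 for MIMAT0004504, 0.44 for MIMAT0004776 and 0.86 for MIMAT0005938. Precision is limited by dim signal, since 693 of 856 features were not above background on any array.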

Other observations

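The tests of array brightness in this part were chosen after the values had been seen, and the test of consecutive accession numbers before. The background threshold that picked the features of the accession test was added after the values had been seen. Features with signal above background were unevenly spread over the accession numbers, which miRBase assigns roughly in order of registration. In accession order, 99 of the first 214 features (46.3%) were above background on at least 1 array, against 10 of the next 214 (4.67%), 25 of the following 214 (11.7%) and 29 of the last 214 (13.6%). The last set held 20 features above background on all 4 arrays, more than the 4 and 6 of the sets between, and the first held 45.

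Features with consecutive accession numbers had similar profiles across the lines. Over 62 such pairs among 162 of the 163 features above background on at least 1 array, the mean correlation of the 4-line profiles was 0.35 after quantile normalization. Shuffling profiles among features of similar level gave 0.02 on average (one-sided permutation p = 7e-05, 100000 permutations). The shuffle was not kept within parts of the accession order, so profiles shared broadly by early or by late accessions would also raise the mean. In the deposited values the mean was 0.78 against 0.39 shuffled, with p = 1e-05, the smallest these permutations can give. MicroRNAs of 1 cluster or family are often registered together, so shared transcription and probes that bind each other's targets are both candidate explanations. Neither was tested, because no sequence or position was used here.

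The arrays of the 4 lines differed in the size and rank of signals above background. One brightness factor per array would leave few features away from a pair's median ratio. In KYSE-520 with KYSE-890, 58.8% of the 17 features over 5 times the background threshold on both arrays lay more than 2-fold from it. The share was 41.2% of 17 in KYSE-450 with KYSE-890. It was 28.6% of 14 in KYSE-450 with KYSE-960 and 46.2% of 13 in KYSE-520 with KYSE-960. In KYSE-450 with KYSE-520 it was 8.89% of 45, and in KYSE-890 with KYSE-960 9.09% of 11, which is 1 feature. Most of these sets are small. A level-dependent curve per array keeps the order of features, yet 27 pairs of features were ordered one way by at least 4-fold in KYSE-520 and the other way by at least 4-fold in KYSE-890, and 15 remained without MIMAT0005864, the feature most involved. KYSE-450 with KYSE-890 had 14, or 9 without that feature. KYSE-450 with KYSE-960 had 2, KYSE-520 with KYSE-960 had 5 and the 2 closest pairs had 0. Such a curve alone would leave 0 reordered pairs, so the 27 argue against it as the whole cause for KYSE-520 with KYSE-890. They involve 26 features, so they are not independent, and with 1 array per line the measurement error is not known. The 14, 5 and 2 are also above 0. The limit for counting against the curve was chosen after the values had been seen. The 5 and 2 fell short of it with all features, and the 14 only without the feature most involved. For these pairs and the 2 closest pairs the curve stays open. A constant background offset was excluded as the whole cause. Array medians differed by at most 8.0 intensity units, while the median difference of features above background reached 467.5. What also stays open is a difference between the lines themselves, which the design names and which was not tested, or RNA recovery or labelling that differed between arrays for some features only. With 1 array per line these cannot be told apart.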
